A study of Homo sapiens with 6 samples.

How the data were processed

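RNA sequencing of THP-1 cells gave 6 libraries, 3 called RNAi-Ctrl and 3 called RNAi-ABCA1-seRNA in the labels. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a NEBNext Ultra RNA kit. The sample descriptions call the control libraries WT and the others sh, each with the replicate number. The labels therefore leave open whether control cells carried a control RNAi construct. The authors deposited 1 table of raw read counts per gene, with 1 column per library, and no normalization. The submitters' processing notes name STAR, HTSeq 0.6.0, DESeq2 and the build hg38, without saying what each was used for. The gene annotation, the strand setting of the counting and any filter are not given in the sources used here, so reads from overlapping or antisense genes, and from near-identical genes, may be missing or misassigned.

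The table had 19932 genes by symbol, and all 19932 matched a gene name of GENCODE v29 (GRCh38), which supplied identifiers, positions, transcript lengths, GC content and the share of exon sequence overlapping other genes. Of these, 19907 were protein-coding and 25 of other types, and 2092 had 0 counts in all libraries. No row named something other than a gene. Unused columns of other samples numbered 0. A prepared list of abundant nuclear and noncoding RNAs had 0 members among the genes of the table and gave no result.

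Total counts ranged from 18560544 to 23953640 per library, so that 3 counts, the limit that a count of 0 allows, equal 0.125 to 0.162 CPM. Between 3743 and 5258 genes had 0 counts in a library. Within groups, pairs of libraries differed by more than sampling noise, which alone gives a chi-square over degrees of freedom of 1. The values were 2.53 to 4.99 in RNAi-Ctrl and 9.47 to 28.0 in RNAi-ABCA1-seRNA. The libraries thus differed by more than repeated reading of 1 library would give, and all 6 were counted as separate samples. Such an excess does not show that they came from separate cultures.

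From the counts, edgeR 4.0.16 in R 4.3.3 was used with TMM scaling (factors 0.925 to 0.938 in RNAi-Ctrl and 1.06 to 1.10 in RNAi-ABCA1-seRNA) and its default filter on low counts (minimum count 10, minimum total 15), which left 12832 genes. Its quasi-likelihood F test, two-sided, compared the groups with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The biological coefficient of variation was 9.34%. Log2 CPM used a prior count of 2. For a gene with 0 counts in a group the fold is a lower bound against 3 counts over the group, and for the genes with the largest changes, and others with 1 to 3 counts in a group, the ratio of counts is given with its exact 95% interval, which covers counting error only, since PCR reads without molecular identifiers are not independent.

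Before the data were examined, 36 gene lists were fixed, together with the comparisons, the alternatives and the rule for naming genes, and 31 lists had the 5 tested members needed for a test. Each was tested with camera of limma 3.58.1 on log2 CPM, two-sided, with a preset correlation of 0.01, Benjamini-Hochberg adjusted over the 31 lists, and again with an estimated correlation and with fry. Named genes were ABCA1, then the 8 largest positive and 8 largest negative log2 fold changes among genes with an adjusted p under 0.05, a mean of at least 5 CPM and groups that did not overlap, then up to 4 members per list with the lowest adjusted p (up to 2 most abundant where none passed). Any tested member of the LXR, NF-kB cytokine and ABCA1 neighbour lists could also be named. Genes named outside this rule are said to be so, and some genes that the rule selected are not reported here.

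Alternatives were DESeq2's size factors, library totals alone, no filter, a filter of 5 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, and stricter thresholds. GC and transcript length offsets, fitted per library by loess with a span of 0.3, were added after seeing the data. The main procedure was tested on simulated data with 200 changed genes, of which 193 were tested among 12229 genes. There, 88.7% of the 2-fold and 99% of the 4-fold changes were recovered. Of 200 called genes 19 were unchanged ones, a larger share than the adjusted p threshold aims for. Few genes changed in the simulation, whereas 9625 of 12832 tested genes were called in the real data. The simulation therefore cannot show how the procedure performs where most genes change. No conclusion about the real comparison is drawn from it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.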

Results

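Gene expression was measured by RNA sequencing in THP-1, a human monocytic leukaemia line that is widely used as a model of monocytes and macrophages. Cells with RNA interference (RNAi) against an enhancer RNA of the ABCA1 locus, called RNAi-ABCA1-seRNA, were compared with cells called RNAi-Ctrl, with 3 libraries in each group. ABCA1 encodes the membrane transporter that passes cholesterol from cells to lipid-poor apolipoprotein A-I. The comparison asked how transcript levels differed between cells given RNAi against the enhancer RNA and control cells, with cholesterol efflux and macrophage inflammation named as the subject of the series. Total counts were 18560544, 18609734 and 23953640 in RNAi-Ctrl replicates 1, 2 and 3, and 22272954, 20408164 and 19049147 in RNAi-ABCA1-seRNA replicates 1, 2 and 3. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The count table held almost only protein-coding genes and no row for the enhancer RNA, so the RNAi target was not measured and the knockdown could not be checked in any library. Expression values below are in CPM (counts relative to library totals scaled by the trimmed mean of M values, TMM), as mean ± SD of 3 libraries per group. Log2 fold changes are RNAi-ABCA1-seRNA over RNAi-Ctrl ± SE. Genes said to have risen or fallen passed edgeR's quasi-likelihood test at an adjusted p under 0.05.

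ABCA1 itself (ENSG00000165029.15, minus strand of chromosome 9, 104781002 to 104928237 in GRCh38) differed between the groups by less than the spread between libraries. Its level was 384.5 ± 40.4 CPM in RNAi-Ctrl and 350.3 ± 76.8 CPM in RNAi-ABCA1-seRNA. Single libraries gave 339.8, 419 and 395 CPM in RNAi-Ctrl and 264, 410.4 and 377 CPM in RNAi-ABCA1-seRNA, from 5911 to 9197 counts each. The log2 fold change was -0.13 ± 0.14 (95% confidence interval -0.44 to 0.18), with an adjusted p of 0.401 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The direction turned to 0.058 (adjusted p = 0.503 in the same edgeR quasi-likelihood test) without RNAi-ABCA1-seRNA replicate 1, the library with the lowest value. It was 0.075 (adjusted p = 0.652 in that edgeR test) when libraries were scaled by their totals alone. With GC and length trends of each library removed, a setting chosen after seeing the data, the value was 0.20 (95% confidence interval 0.04 to 0.35) and passed edgeR's quasi-likelihood test at an adjusted p of 0.0259, on the higher side.

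Genes around ABCA1 on chromosome 9 went both ways. Of 9 tested genes of this neighbourhood, ABCA1 included, 3 were higher, 3 were lower and 3 did not pass, with the same counts adjusted over the list alone. SMC2, a condensin subunit used in mitosis, rose from 15.5 ± 1.301 to 77.5 ± 4.55 CPM (log2 fold change 2.32 ± 0.095). FSD1L rose from 9.53 ± 0.951 to 28.9 ± 5.84 CPM (log2 fold change 1.6 ± 0.15). ZNF462 fell from 18.2 ± 0.592 to 2.99 ± 0.833 CPM (log2 fold change -2.61 ± 0.18). SLC44A1, a choline transporter, fell from 159.6 ± 4.37 to 107 ± 8.85 CPM (log2 fold change -0.57 ± 0.078). TMEM38B fell from 36.4 ± 1.41 to 26.1 ± 0.915 CPM (log2 fold change -0.48 ± 0.083). NIPSNAP3B, the remaining higher gene, had a log2 fold change of 0.71 ± 0.28 at about 2 CPM or less, and its call was lost in several alternatives, among them each fit without RNAi-Ctrl replicate 2 or 3 or without RNAi-ABCA1-seRNA replicate 2 (0.66, 0.62 and 0.59). NIPSNAP3A (0.069 ± 0.11) did not pass, but did by edgeR's quasi-likelihood test with scaling by library totals alone (0.27, adjusted p = 0.0387). The list did not stand apart from other genes (camera adjusted p = 0.951), and its median of -0.04 turned positive with scaling by library totals and with GC and length trends removed.

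Across the transcriptome the 2 groups differed widely. Of 12832 tested genes, 4905 were higher and 4720 were lower in RNAi-ABCA1-seRNA, 75.01% of those tested, by edgeR's quasi-likelihood test at an adjusted p under 0.05. Among them 2593 higher and 2087 lower genes had an absolute log2 fold change of at least 1, and 1255 were higher and 855 lower by at least 4-fold. The 3 libraries of one group lay above all 3 of the other for 10052 genes, 78.3% of those tested, where chance gives 10%. The first principal component, which parted the groups, held 93.7% of the variance. Libraries of one group correlated at Spearman 0.991 to 0.997 across genes, and libraries of different groups at 0.847 to 0.863. RNAi-ABCA1-seRNA replicate 1 stood farthest from its group, with 5258 genes at 0 counts against 3836 and 4444 in the other 2, and without it 5117 genes were higher and 4781 lower. Scaling by library totals alone moved the median of all genes by 0.21 on the log2 scale relative to TMM and gave 6019 higher and 3684 lower genes, 62.0% higher in place of 51.0%, so that small changes depend on the scaling.

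**Figure D1:**
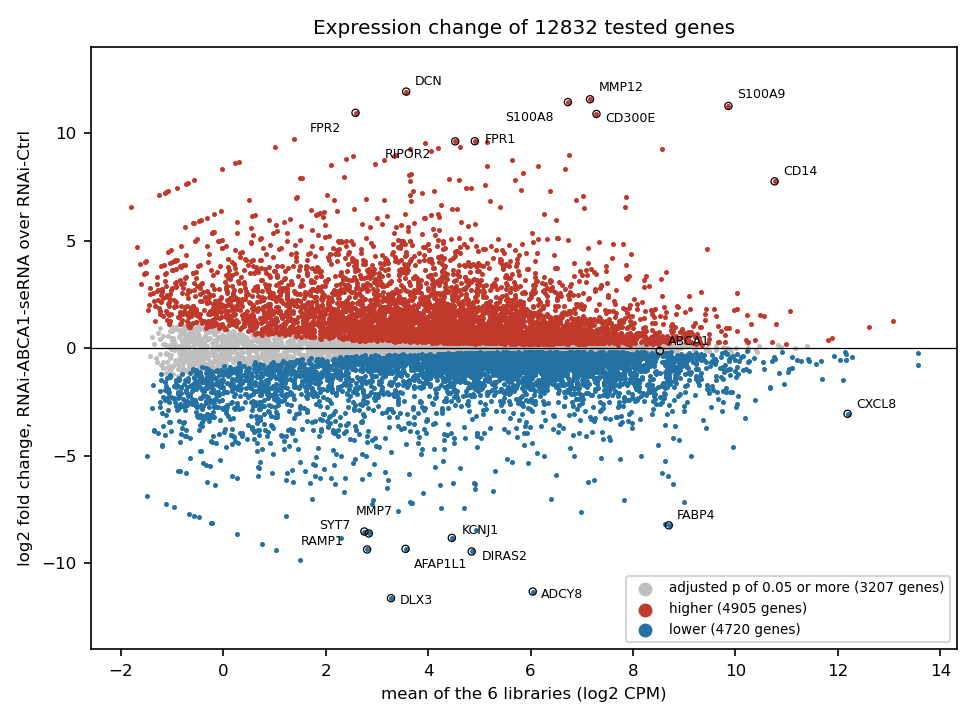
Mean expression of each tested gene over the 6 libraries (log2 CPM, horizontal axis) against its log2 fold change, RNAi-ABCA1-seRNA over RNAi-Ctrl (vertical axis). Each point is 1 gene, coloured by whether it was higher (4905), lower (4720) or did not pass; labelled genes include ABCA1 near 0 and, at the edges, genes with few or 0 counts in one group, whose plotted values are fitted and not bounds.

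The 8 genes with the largest increases by the naming rule were of several kinds. S100A9, a calcium-binding protein abundant in neutrophils and monocytes, rose from 0.735 ± 0.302 to 1861 ± 384 CPM, a ratio of 2474 (95% counting interval 1837 to 3419). Its partner S100A8 rose from 0.0644 ± 0.068 to 212 ± 72.4 CPM (ratio 3034, interval 1185 to 11137). MMP12, the macrophage elastase, rose from 0.0919 ± 0.0405 to 286 ± 61.3 CPM (ratio 3222, interval 1380.2 to 9923). CD300E, an activating receptor of monocytes, rose from 0.173 ± 0.153 to 312 ± 21.8 CPM (ratio 1963, interval 1034 to 4293). The formyl peptide receptor gene FPR1 rose from 0.0602 ± 0.104 to 60.04 ± 8.57 CPM (ratio 848, interval 331 to 3114). FPR2 had 0 counts in RNAi-Ctrl and was at least 225-fold higher in RNAi-ABCA1-seRNA at 11.96 ± 1.58 CPM. RIPOR2, with 3 counts over the RNAi-Ctrl group, had a ratio of 870 (interval 297 to 4221). DCN, the gene of the proteoglycan decorin and a marker of fibroblasts, had 0 counts in RNAi-Ctrl and was at least 443-fold higher at 23.7 ± 8.03 CPM, the bounds being set against 3 counts over the group.

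The 8 genes with the largest decreases by that rule follow. ADCY8, an adenylyl cyclase, fell from 132 ± 5.31 to 0.0439 ± 0.0446 CPM on 3 counts in RNAi-ABCA1-seRNA, a ratio of 2908 (interval 995 to 14102). DIRAS2, a small GTPase, fell from 57.5 ± 4.81 to 0.0823 ± 0.143 CPM (ratio 761, interval 326 to 2346). KCNJ1, a potassium channel, fell from 43.96 ± 3.11 to 0.0886 ± 0.0388 CPM (ratio 483, interval 222 to 1318). The homeobox gene DLX3 went from 19.3 ± 0.779 CPM to 0 counts in all 3 RNAi-ABCA1-seRNA libraries, at least 428-fold lower. RAMP1 fell to 1 count (ratio 931, interval 167 to 36828), AFAP1L1 to 2 counts (ratio 777, interval 215 to 6426), SYT7 to 2 counts (ratio 473, interval 130.4 to 3909) and the matrix metalloproteinase gene MMP7 to 2 counts (ratio 443, interval 122 to 3669). These intervals and bounds cover counting error only.

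Genes of cholesterol synthesis and low-density lipoprotein uptake were lower as a group in RNAi-ABCA1-seRNA. Of 25 tested members, 22 fell, 1 rose and 2 did not pass, with the same counts adjusted over the list alone. The median was -1.66 (camera adjusted p = 4.85e-07; adjusted p = 0.0817 with an estimated correlation). STARD4, a sterol carrier, fell from 227 ± 2.71 to 22.1 ± 2.15 CPM (log2 fold change -3.36 ± 0.088). HMGCS1 fell from 363 ± 10.2 to 63.1 ± 6.78 CPM (log2 fold change -2.52 ± 0.089). The gene that rose was PMVK (0.89 ± 0.13) and those that did not pass were EBP (0.12 ± 0.094) and TM7SF2 (-0.11 ± 0.12), all 3 named after their values were seen.

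Targets of the liver X receptors (LXR) and genes of cholesterol efflux were split. Of 22 tested members, 7 rose, 11 fell and 4 did not pass, with the same counts adjusted over the list alone. ABCG1, a second cholesterol exporter, rose from 2.95 ± 0.132 to 11.5 ± 0.518 CPM (log2 fold change 1.96 ± 0.14). ABCA7 rose from 15.2 ± 1.59 to 54.4 ± 5.75 CPM (log2 fold change 1.84 ± 0.11). SMPDL3A rose from 6.13 ± 0.951 to 133 ± 12.4 CPM (log2 fold change 4.43 ± 0.12). The apolipoprotein genes APOE and APOC1 fell, from 327 ± 16.2 to 157 ± 26.2 CPM (log2 fold change -1.06 ± 0.11) and from 102 ± 4.44 to 12.2 ± 1.99 CPM (log2 fold change -3.05 ± 0.11). Other members that fell included PLIN2, a lipid droplet coat protein, from 1118 ± 42.1 to 297 ± 43.5 CPM (log2 fold change -1.91 ± 0.1), the desaturase gene SCD from 604 ± 31.9 to 209.9 ± 17.5 CPM (log2 fold change -1.53 ± 0.081), LPL, the lipoprotein lipase, from 771 ± 7.896 to 20.03 ± 2.498 CPM (log2 fold change -5.27 ± 0.1), and FABP4, a fatty acid carrier, from 828 ± 49.7 to 2.6998 ± 0.716 CPM (log2 fold change -8.24 ± 0.15). NPC1, which exports cholesterol from lysosomes, fell from 85.6 ± 4.43 to 30.04 ± 2.801 CPM (log2 fold change -1.51 ± 0.091). Besides ABCA1, the genes that did not pass were LPCAT3 (0.26 ± 0.17; 65.6% of its exon sequence overlaps another gene), NR1H3, which encodes LXR alpha (-0.04 ± 0.077), and SREBF1 (-0.15 ± 0.075), and with scaling by library totals NR1H3 and SREBF1 turned to 0.17 and 0.056. By edgeR's quasi-likelihood test LPCAT3 passed on the higher side with that scaling (0.47, adjusted p = 0.0314), and SREBF1 passed on the lower side without RNAi-ABCA1-seRNA replicate 1 (-0.18, adjusted p = 0.0185). The list's median was -0.2 and its mean -0.7 (camera adjusted p = 0.317), and the median was 0.0045 with scaling by library totals. The directional fry test, which asks only whether the members moved one way on balance, gave an adjusted p of 6.93e-05 on the lower side.

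Fatty acid synthesis and lipoprotein uptake genes were mostly lower. In the fatty acid and triglyceride list 13 of 19 fell, 3 rose and 3 did not pass, with the same counts adjusted over the list alone. The median was -0.38 (camera adjusted p = 0.00859; adjusted p = 0.341 with an estimated correlation). MLXIPL, a carbohydrate-responsive transcription factor, fell from 250.5 ± 6.08 to 1.27 ± 0.22 CPM (log2 fold change -7.62 ± 0.12). FASN, the fatty acid synthase, fell from 1069.9 ± 67.8 to 320.3 ± 28.8 CPM (log2 fold change -1.74 ± 0.084). DGAT2, which makes triglycerides, fell from 90.04 ± 1.92 to 24.6 ± 2.74 CPM (log2 fold change -1.87 ± 0.093). Named after their values were seen, the genes that rose were AGPAT2 (1.34 ± 0.11), GPAM (0.45 ± 0.15) and ACSS2 (0.35 ± 0.08), and SREBF1, ELOVL5 and ACSL3 did not pass. In the list of lipoprotein uptake and cholesteryl ester handling 11 of 17 fell, 4 rose and 2 did not pass, again with the same counts adjusted over the list alone. The median was -0.84 (camera adjusted p = 0.0397; adjusted p = 0.23 with an estimated correlation). The scavenger receptor genes OLR1 and CD36 fell, from 37.1 ± 0.464 to 0.441 ± 0.0887 CPM (log2 fold change -6.39 ± 0.15) and from 441 ± 14.4 to 56.5 ± 1.46 CPM (log2 fold change -2.97 ± 0.072). LIPA, the lysosomal acid lipase, fell from 2113 ± 34.7 to 223 ± 19.04 CPM (log2 fold change -3.25 ± 0.08). The 4 that rose, named after their values were seen, were the scavenger receptor gene MARCO (8.08 ± 0.29), LIPE (2.19 ± 0.2), CXCL16 (1.37 ± 0.081) and LRP1 (1.12 ± 0.12), and SCARB1 and NCEH1 did not pass. This list's call was lost without RNAi-ABCA1-seRNA replicate 2 (camera adjusted p = 0.0518), with the replicate number as a block (0.0684) and with GC and length trends removed (0.0868).

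**Figure D2:**
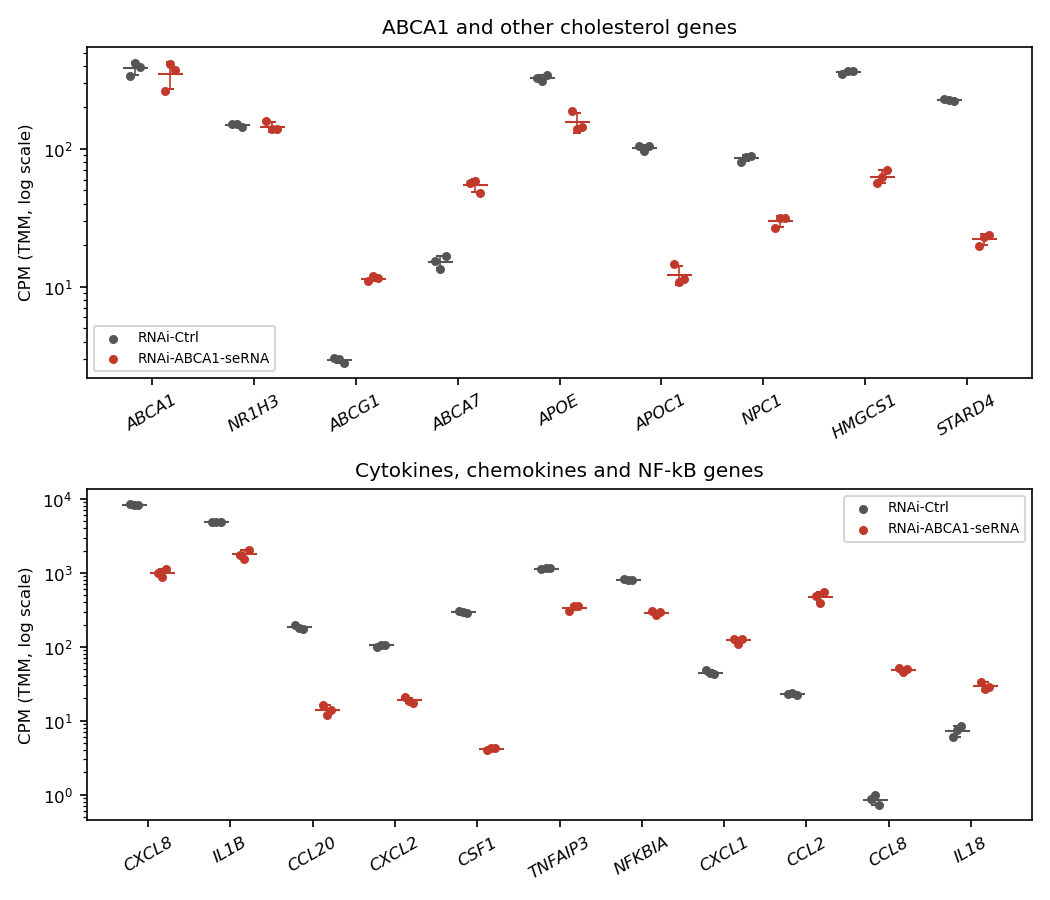
Levels of cholesterol genes (upper panel) and of cytokine, chemokine and NF-kB genes (lower panel) in CPM on a log axis, with 1 point per library for RNAi-Ctrl (grey) and RNAi-ABCA1-seRNA (red); the horizontal mark is the mean and the bar the SD of 3 libraries. ABCA1 and NR1H3 overlap between the groups, while the 3 libraries of each group stay apart for HMGCS1 and CXCL8, which fell, and for CCL2, which rose.

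Inflammatory cytokine and chemokine genes regulated by NF-kB did not move one way. Of 23 tested members, 13 rose, 8 fell and 2 did not pass, with the same counts adjusted over the list alone. CXCL8, the neutrophil chemokine interleukin 8, fell from 8340.1 ± 111 to 1001 ± 115 CPM (log2 fold change -3.06 ± 0.089). IL1B, the gene of interleukin 1 beta, fell from 4843 ± 41.7 to 1784 ± 259.9 CPM (log2 fold change -1.44 ± 0.095). CCL20 fell from 184 ± 9.93 to 14.03 ± 2.07 CPM (log2 fold change -3.71 ± 0.11). CXCL2 fell from 104 ± 3.58 to 18.9 ± 1.63 CPM (log2 fold change -2.47 ± 0.089). CSF1, the macrophage growth factor, fell from 297 ± 7.95 to 4.19 ± 0.188 CPM (log2 fold change -6.14 ± 0.091). The monocyte chemokine genes CCL2 and CCL8 rose, from 23.03 ± 0.886 to 477 ± 77.3 CPM (log2 fold change 4.37 ± 0.12) and from 0.856 ± 0.13 to 49.3 ± 3.16 CPM (log2 fold change 5.85 ± 0.14). IL18 rose from 7.296 ± 1.19 to 29.63 ± 3.51 CPM (log2 fold change 2.01 ± 0.14). CXCL1 rose from 44.9 ± 2.98 to 122 ± 10.7 CPM (log2 fold change 1.45 ± 0.09). TNFSF10 rose from 0.878 ± 0.291 to 34.2 ± 1.48 CPM (log2 fold change 5.27 ± 0.17). IL6, with 2 counts in RNAi-Ctrl, rose to 15.5 ± 2.46 CPM, a ratio of 441 (95% counting interval 122 to 3649.9). PTGS2 (-0.17 ± 0.17) and IL1A (0.15 ± 0.15) did not pass; without RNAi-ABCA1-seRNA replicate 3, PTGS2 was at -0.41 with an adjusted p of 0.0118 by edgeR's quasi-likelihood test, and without replicate 1 at 0.019. With scaling by library totals alone IL1A was at 0.35 and passed the edgeR quasi-likelihood test (adjusted p = 0.0499). The list's median was 0.91 and its mean 0.83 (camera adjusted p = 0.607), whereas fry gave the lower direction (adjusted p = 0.03), a difference in sign. TNF, CCL3 and CCL4 were listed at 0 counts in all 6 libraries, as were genes that nearly all cells use, such as TUBB and DDX39B, so their expression could not be assessed.

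Genes of the NF-kB pathway and its feedback were lower in RNAi-ABCA1-seRNA. Of 26 tested members, 22 fell, 3 rose and 1 did not pass, unchanged when adjusted over the list alone. The median was -0.95 (camera adjusted p = 0.000159; adjusted p = 0.23 with an estimated correlation). TRAF1 fell from 1284 ± 28.4 to 98.1 ± 1.53 CPM (log2 fold change -3.71 ± 0.07). TNFAIP3, the feedback inhibitor A20, fell from 1143 ± 23.4 to 339 ± 29.2 CPM (log2 fold change -1.75 ± 0.078). NFKB1 fell from 474 ± 8.17 to 170.1 ± 7.96 CPM (log2 fold change -1.48 ± 0.069). NFKBIA, the inhibitor I-kappa-B alpha, fell from 808 ± 11.3 to 291 ± 16.7 CPM (log2 fold change -1.48 ± 0.07). TNIP3 (1.31 ± 0.22), IRAK3 (0.88 ± 0.11) and MYD88 (0.78 ± 0.071) rose and BCL3 (0.14 ± 0.074) did not pass, named after their values were seen. Immediate early genes, which respond within minutes to growth factors and stress, fell as well, 20 of 27 against 3 that rose and 4 that did not pass, with the same counts adjusted over the list alone. Their median was -1.0 (camera adjusted p = 7.16e-05; adjusted p = 0.338 with an estimated correlation). EGR2 fell from 449 ± 15.3 to 3.39 ± 0.971 CPM (log2 fold change -7.06 ± 0.15). ATF3 fell from 745 ± 9.27 to 13.3 ± 1.51 CPM (log2 fold change -5.8 ± 0.099). DUSP5 fell from 173 ± 0.418 to 14.3 ± 0.115 CPM (log2 fold change -3.59 ± 0.076). JUN fell from 535 ± 8.26 to 134 ± 4.196 CPM (log2 fold change -2.0 ± 0.067). NR4A1 (1.56 ± 0.24), NR4A2 (1.44 ± 0.26) and ZFP36 (0.66 ± 0.068) rose, while FOS, EGR3, IER2 and KLF2 did not pass, also named after their values were seen.

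Inflammasome genes split. Of 15 tested members 9 rose, 5 fell and 1, CASP4, did not pass, with the same counts adjusted over the list alone. The median was 1.7 (camera adjusted p = 0.266). CASP1, the protease that matures interleukin 1 beta, rose from 16.1 ± 0.951 to 132 ± 7.44 CPM (log2 fold change 3.03 ± 0.088). MEFV, the gene of pyrin, rose from 6.22 ± 0.97 to 88.9 ± 6.52 CPM (log2 fold change 3.82 ± 0.12). NLRP3, the sensor of the best-known inflammasome, fell from 289 ± 5.99 to 72.2 ± 3.86 CPM (log2 fold change -2.0 ± 0.073). P2RX7, its ATP-gated channel, fell from 376 ± 13.8 to 76.9 ± 10.7 CPM (log2 fold change -2.29 ± 0.098). The other genes that fell were IL1B, CARD8 (-0.54 ± 0.091) and NINJ1 (-0.96 ± 0.085), the last 2 and CASP4 being named after their values were seen.

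Interferon-stimulated genes were higher. Of 36 tested members, 33 rose, 2 fell and 1 did not pass, or 34 and 2 adjusted over the list alone. The median was 1.33 (camera adjusted p = 2.55e-06; adjusted p = 0.45 with an estimated correlation). IFITM3, which blocks virus entry, rose from 43.2 ± 3.797 to 440.2 ± 98.1 CPM (log2 fold change 3.35 ± 0.15). TRIM22 rose from 6.53 ± 1.37 to 58.6 ± 7.05 CPM (log2 fold change 3.16 ± 0.15). IFI44 rose from 6.33 ± 0.563 to 55.7 ± 10.2 CPM (log2 fold change 3.14 ± 0.15). IFITM1 rose from 4.12 ± 0.431 to 127 ± 36.1 CPM (log2 fold change 4.95 ± 0.21), though 32.5% of its exon sequence overlaps another gene and its paralogs can share reads. The genes that fell were IRF7 (-1.28 ± 0.13) and DDX60 (-0.31 ± 0.11), and HERC6 (0.26 ± 0.11) did not pass, named after their values were seen.

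All 7 tested genes of MHC class II presentation rose, and all did adjusted over the list alone. The median was 2.27 (camera adjusted p = 0.00374; adjusted p = 0.23 with an estimated correlation). HLA-DRB1 rose from 36.7 ± 0.848 to 177 ± 22.7 CPM (log2 fold change 2.27 ± 0.099). HLA-DRB5 rose from 9.26 ± 1.04 to 66.3 ± 6.701 CPM (log2 fold change 2.83 ± 0.12). HLA-DQB1 rose from 1.84 ± 0.468 to 19.7 ± 2.96 CPM (log2 fold change 3.44 ± 0.2). HLA-DQA1 rose from 0.135 ± 0.186 to 11.6 ± 1.12 CPM (log2 fold change 6.49 ± 0.4). Values of these near-identical genes are uncertain, because reads shared between paralogs can be split or dropped in counting. In class I presentation 4 of 6 rose and 2 fell, with the same counts adjusted over the list alone. The median was 0.82 (camera adjusted p = 0.457). NLRC5, the class I transactivator, rose from 49.6 ± 1.08 to 144 ± 14.99 CPM (log2 fold change 1.54 ± 0.088). B2M rose from 364 ± 10.9 to 828 ± 129 CPM (log2 fold change 1.19 ± 0.1), as did PSMB10 (0.45 ± 0.1; 34.8% of its exon sequence overlaps another gene), while ERAP2 (-0.68 ± 0.16) and ERAP1 (-0.38 ± 0.1) fell. ERAP1 was named after its value was seen. Most genes of this region of chromosome 6 were near 0 in all libraries: 140 of the 150 genes from MOG to RGL2 (29656981 to 33299324) had 10 counts or fewer over the 6 libraries, and HLA-DRA and HLA-DPA1 had 0, so these lists rest on few of their members.

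Markers of monocytes and macrophages were mostly higher, with exceptions. Of 32 tested members, 21 rose, 10 fell and 1, SPP1 (0.043 ± 0.091, named after its value was seen), did not pass, with the same counts adjusted over the list alone. The median was 1.02 (camera adjusted p = 0.0126; adjusted p = 0.23 with an estimated correlation). CD14, the endotoxin co-receptor, rose from 16.1 ± 0.567 to 3462 ± 441 CPM (log2 fold change 7.75 ± 0.12). CD163, the haemoglobin scavenger receptor, rose from 2.84 ± 0.549 to 261 ± 21.3 CPM (log2 fold change 6.5 ± 0.13). The costimulatory gene CD86 rose from 0.462 ± 0.0978 to 103 ± 10.3 CPM (log2 fold change 7.8 ± 0.16). The complement gene C1QC rose from 0.423 ± 0.259 to 216 ± 16.1 CPM (log2 fold change 8.98 ± 0.19). EGR2, already described, was among those that fell, as were ITGAX (-2.35 ± 0.083), CHIT1 (-2.82 ± 0.35), MERTK (-0.59 ± 0.083), CSF1R (-0.39 ± 0.079) and CD68 (-0.25 ± 0.071), named after their values were seen. Genes of alternative (M2) activation split into 9 that rose, 7 that fell and 1, CCL22 (0.7 ± 0.31, named after its value was seen), that did not pass, out of 17, or 10 and 7 adjusted over the list alone. The median was 0.7 (camera adjusted p = 0.74). The decoy receptor gene IL1R2 rose from 0.0918 ± 0.0701 to 71.2 ± 13.7 CPM (log2 fold change 9.56 ± 0.29). The scavenger receptor gene MSR1 fell from 124 ± 6.06 to 5.73 ± 1.07 CPM (log2 fold change -4.43 ± 0.12). The transglutaminase gene TGM2 fell from 89.2 ± 1.68 to 11.1 ± 0.838 CPM (log2 fold change -3.0 ± 0.089).

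Granule and progenitor genes of the myeloid lineage rose, 12 of 13 with 1, FLT3 (-0.35 ± 0.22, named after its value was seen), that did not pass, and the same counts adjusted over the list alone. Their median was 2.52 (camera adjusted p = 0.00051; adjusted p = 0.341 with an estimated correlation). MYB, a transcription factor of blood progenitors, rose from 19.2 ± 0.706 to 230.2 ± 35.4 CPM (log2 fold change 3.58 ± 0.12). The granule proteoglycan gene SRGN rose from 467 ± 23.5 to 1627 ± 125 CPM (log2 fold change 1.8 ± 0.078). MS4A3 rose from 0.111 ± 0.104 to 9.24 ± 1.76 CPM (log2 fold change 6.37 ± 0.37). RNASE2, an eosinophil granule ribonuclease, rose from 90.9 ± 1.19 to 298 ± 45.2 CPM (log2 fold change 1.71 ± 0.1).

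Cell cycle genes were higher in RNAi-ABCA1-seRNA. All 37 tested genes of G2/M and mitosis rose, also adjusted over the list alone. The median was 3.47 (camera adjusted p = 7.53e-13; adjusted p = 0.0817 with an estimated correlation). TOP2A, the topoisomerase of dividing cells, rose from 16.5 ± 0.216 to 260.2 ± 22.05 CPM (log2 fold change 3.98 ± 0.091). The mitotic kinase gene CDK1 rose from 5.43 ± 0.835 to 91.1 ± 5.08 CPM (log2 fold change 4.06 ± 0.12). The spindle gene TPX2 rose from 8.82 ± 0.998 to 114 ± 6.9997 CPM (log2 fold change 3.69 ± 0.1) and FOXM1, a transcription factor of mitotic genes with 15.9% of its exon sequence shared with another gene, rose from 3.72 ± 0.283 to 52.9 ± 4.26 CPM (log2 fold change 3.83 ± 0.11). Of 38 genes of S phase and DNA replication 37 rose and 1, GINS3 (-0.5 ± 0.1, named after its value was seen), fell, with the same counts adjusted over the list alone. The median was 2.92 (camera adjusted p = 8.23e-13; adjusted p = 0.23 with an estimated correlation). The replicative helicase genes MCM4 and MCM3 rose, from 26.2 ± 1.11 to 283 ± 7.89 CPM (log2 fold change 3.44 ± 0.077) and from 28.6 ± 0.79 to 243 ± 17.9 CPM (log2 fold change 3.09 ± 0.084). UHRF1 rose from 7.99 ± 0.875 to 83.99 ± 2.79 CPM (log2 fold change 3.39 ± 0.1). TYMS, the thymidylate synthase, rose from 2.64 ± 0.374 to 60.2 ± 1.66 CPM (log2 fold change 4.52 ± 0.12), with 39.1% of its exon sequence overlapping another gene.

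Replication-dependent histone genes could be assessed only in part, since 10 of the 19 listed genes had enough counts to be tested. Of the 10 tested, 7 fell, HIST1H1C (1.16 ± 0.3) and HIST2H2AC (2.11 ± 0.52) rose and HIST1H2AG did not pass, with the same counts adjusted over the list alone. HIST1H1C, HIST2H2AC and HIST1H2AG were named after their values were seen. HIST1H2BK fell from 24.2 ± 0.345 to 4.39 ± 0.551 CPM (log2 fold change -2.47 ± 0.12). HIST1H2AC fell from 9.81 ± 1.501 to 2.76 ± 0.438 CPM (log2 fold change -1.82 ± 0.18), and reads shared between near-identical histone genes leave their values uncertain. The list's median was -1.57 and it did not pass (camera adjusted p = 0.0757), but did on the lower side with scaling by library totals (camera adjusted p = 0.0300). Targets of p53 gave 4 that rose, 10 that fell and 8 that did not pass of 22, the same adjusted over the list alone. The median was -0.22 (camera adjusted p = 0.107, and 0.0379 without RNAi-ABCA1-seRNA replicate 3 and 0.0316 with a stricter filter on low counts, both on the lower side). GDF15, a stress-induced cytokine, fell from 1085 ± 22.04 to 33.1 ± 3.11 CPM (log2 fold change -5.03 ± 0.092). PLK3 fell from 322 ± 6.53 to 16.99 ± 1.52 CPM (log2 fold change -4.24 ± 0.088). PHLDA3 fell from 31.6 ± 1.37 to 2.69 ± 0.284 CPM (log2 fold change -3.54 ± 0.12). BTG2, an inhibitor of proliferation, fell from 979 ± 14.2 to 213 ± 22.02 CPM (log2 fold change -2.2 ± 0.083). FAS (4.67 ± 0.44), FDXR (2.37 ± 0.27), DDB2 (2.31 ± 0.1) and POLH (0.44 ± 0.093) rose, named after their values were seen.

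Stress and metabolic lists held changes in both directions. In the unfolded protein and integrated stress response 10 of 26 rose and 16 fell, the same adjusted over the list alone. The median was -0.6 (camera adjusted p = 0.317). ATF3, described above, fell, as did the asparagine synthetase gene ASNS, from 73.8 ± 2.74 to 11.6 ± 0.633 CPM (log2 fold change -2.66 ± 0.088), while the folding enzyme gene PDIA4 rose from 115 ± 4.28 to 358 ± 17.3 CPM (log2 fold change 1.64 ± 0.072). In the heat shock and oxidative stress list 10 of 24 rose, 11 fell and 3, HSPH1, HSPE1 and HMOX1 (named after their values were seen), did not pass, the same adjusted over the list alone. The median was -0.016, positive with scaling by library totals (camera adjusted p = 0.607). The antioxidant genes TXNRD1 and SLC7A11 fell, from 1278 ± 4.41 to 192 ± 12.96 CPM (log2 fold change -2.74 ± 0.074) and from 723 ± 70.8 to 85.8 ± 14.5 CPM (log2 fold change -3.08 ± 0.13). The metallothionein gene MT1F, whose close paralogs can share its reads, rose from 1.81 ± 0.212 to 35.997 ± 9.28 CPM (log2 fold change 4.3 ± 0.21). Glycolysis and hypoxia genes gave 17 that rose, 11 that fell and 2, HK2 and ADM (named after their values were seen), that did not pass of 30, the same adjusted over the list alone. The median was 0.36 (camera adjusted p = 0.457). HK1, a hexokinase, rose from 149 ± 3.99 to 501 ± 33.2 CPM (log2 fold change 1.75 ± 0.074). NDRG1 rose from 86.4 ± 5.73 to 266 ± 1.42 CPM (log2 fold change 1.62 ± 0.074). PFKFB4 fell from 104 ± 2.19 to 27.9 ± 2.46 CPM (log2 fold change -1.9 ± 0.086).

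Messenger RNAs encoded in the mitochondrial genome were lower, 10 of 13, and MT-ND3, MT-ND6 and MT-ATP8 did not pass (named after their values were seen), the same adjusted over the list alone. The median was -0.56 (camera adjusted p = 0.00459; adjusted p = 0.23 with an estimated correlation). MT-CO1, the gene with the highest mean CPM in RNAi-Ctrl, fell from 15163 ± 95.6 to 8920.2 ± 202 CPM (log2 fold change -0.77 ± 0.058). MT-ND1 fell from 2883 ± 18.004 to 1495 ± 146 CPM (log2 fold change -0.95 ± 0.077). Nuclear genes of oxidative phosphorylation gave 9 that rose, 10 that fell and 20 that did not pass of 39, or 7 and 9 adjusted over the list alone. The median was 0.012 (camera adjusted p = 0.892). NDUFB10 rose from 23.7 ± 1.23 to 57.7 ± 11.2 CPM (log2 fold change 1.28 ± 0.13). UQCRC1 fell from 302 ± 7.29 to 209 ± 29.1 CPM (log2 fold change -0.53 ± 0.094). Cytosolic ribosomal protein genes gave 11 that rose, 10 that fell and 30 that did not pass of 51, or 5 and 9 adjusted over the list alone. The median was 0.023 (camera adjusted p = 0.892). RPSA rose from 239 ± 1.86 to 421 ± 58.98 CPM (log2 fold change 0.82 ± 0.094), and reads shared with processed pseudogenes leave such values uncertain. Mean log2 CPM of the ribosomal list was 8.44, 7.86 and 8.14 in RNAi-ABCA1-seRNA replicates 1, 2 and 3 and that of the oxidative phosphorylation list 6.15, 5.57 and 5.80, so both varied within the group by more than their medians moved, both medians turned negative with GC and length trends removed, and that of oxidative phosphorylation also with the DESeq2 size factors.

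Ribosome biogenesis genes and MYC targets gave 5 that rose, 13 that fell and 11 that did not pass of 29, the same adjusted over the list alone. The median was -0.2, positive with scaling by library totals (camera adjusted p = 0.173, and 0.0353 on the lower side with GC and length trends removed). NPM1 fell from 562 ± 21.4 to 279 ± 27.7 CPM (log2 fold change -1.01 ± 0.082). RRP12 fell from 150.3 ± 3.29 to 73.1 ± 9.11 CPM (log2 fold change -1.04 ± 0.092). NOLC1 rose from 77.02 ± 3.43 to 145 ± 5.35 CPM (log2 fold change 0.91 ± 0.072), and the others that rose, named after their values were seen, were NOP56 (0.73 ± 0.086), RRS1 (0.51 ± 0.099), BOP1 (0.21 ± 0.086) and NCL (0.2 ± 0.075). Lysosomal genes gave 12 that rose, 12 that fell and 7 that did not pass of 31, the same adjusted over the list alone. The median was -0.14, positive with scaling by library totals (camera adjusted p = 0.892). The protease genes CTSZ and LGMN rose, from 450.1 ± 15.1 to 1557 ± 119 CPM (log2 fold change 1.79 ± 0.076) and from 4.16 ± 0.247 to 29.9 ± 2.39 CPM (log2 fold change 2.85 ± 0.12). ATP6V1H, a subunit of the proton pump, fell from 410.5 ± 3.33 to 94.1 ± 7.87 CPM (log2 fold change -2.12 ± 0.079). Subunits of Mediator, the coactivator that links enhancers to RNA polymerase II, gave 10 that rose, 9 that fell and 11 that did not pass of 30, or 8 and 8 adjusted over the list alone. The median was 0.0036, negative with the DESeq2 size factors and with GC and length trends removed (camera adjusted p = 0.951). MED12 fell from 124 ± 9.39 to 55.2 ± 9.902 CPM (log2 fold change -1.16 ± 0.12). MED30 rose from 12.4 ± 0.747 to 22.4 ± 2.395 CPM (log2 fold change 0.85 ± 0.11).

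Genes of the RNAi machinery included all 4 Argonaute genes, which fell. AGO2, the slicing Argonaute, fell from 802 ± 85.2 to 238 ± 56.1 CPM (log2 fold change -1.75 ± 0.15). AGO3 fell from 46.9 ± 0.558 to 9.89 ± 1.23 CPM (log2 fold change -2.25 ± 0.1). AGO1 fell from 52.7 ± 3.23 to 24.2 ± 2.37 CPM (log2 fold change -1.12 ± 0.097). AGO4 fell from 59.5 ± 1.11 to 31.8 ± 3.04 CPM (log2 fold change -0.9 ± 0.09), the direction being the same with library totals alone and with the DESeq2 size factors. Of 13 tested members 6 fell, 1, DROSHA (0.55 ± 0.083, named after its value was seen), rose and 6 did not pass, the same adjusted over the list alone. The median was -0.18, positive with scaling by library totals (camera adjusted p = 0.189).

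Markers of other cell types were at low levels or went both ways. Of 6 tested fibroblast markers 4 rose and 2 fell, the same adjusted over the list alone. The median was 3.51, the same with DCN at its bound (camera adjusted p = 0.317). Besides DCN, COL3A1 rose from 1 count to 1.42 ± 0.133 CPM (ratio 80.7, interval 14.1 to 3219), LUM rose from 2 counts to 1.37 ± 0.0992 CPM (ratio 39.04, interval 10.5 to 327) and PDGFRB rose (1.97 ± 0.35), while FAP fell from 15.1 ± 0.949 to 0.103 ± 0.0469 CPM (log2 fold change -7.08 ± 0.25) and COL1A1 fell (-2.01 ± 0.51), with PDGFRB and COL1A1 named after their values were seen. Endothelial markers gave 2 that rose, 2 that fell and 1, EGFL7 (named after its value was seen), that did not pass, the same adjusted over the list alone. The median was -0.023, positive with scaling by library totals (camera adjusted p = 0.892). VWF fell from 59.7 ± 2.01 to 0.731 ± 0.422 CPM (log2 fold change -6.33 ± 0.2). ERG fell from 1.13 ± 0.265 to 0.0595 ± 0.103 CPM (log2 fold change -4.08 ± 0.73). PECAM1, which monocytes also express, rose from 407 ± 13.9 to 551 ± 31.8 CPM (log2 fold change 0.44 ± 0.07). CLDN5 rose from 0.118 ± 0.102 to 2.37 ± 0.623 CPM (log2 fold change 4.21 ± 0.52). The only tested T and NK cell marker, NKG7, rose from 0.738 ± 0.221 to 28.6 ± 6.04 CPM (log2 fold change 5.3 ± 0.23). Among B cell markers CD22 fell from 58.3 ± 2.64 to 3.37 ± 0.269 CPM (log2 fold change -4.11 ± 0.11). PAX5 fell from 3.23 ± 1.11 to 0.785 ± 0.29 CPM (log2 fold change -2.05 ± 0.35). The 2 tested erythroid and megakaryocyte markers rose, PPBP from 0.126 ± 0.0421 to 1.05 ± 0.245 CPM (log2 fold change 3.02 ± 0.5) and ITGA2B from 0.491 ± 0.347 to 2.03 ± 0.403 CPM (log2 fold change 2.1 ± 0.48). Neither of the 2 tested epithelial markers passed, CDH1 at 1.03 ± 0.64 and KRT8 at 0.35 ± 0.44, although CDH1 passed edgeR's quasi-likelihood test without RNAi-Ctrl replicate 2 (2.08, adjusted p = 0.0271) and without RNAi-ABCA1-seRNA replicate 1 (1.40, adjusted p = 0.0495). For these 4 short lists the counts were the same adjusted over the list alone, and no list test was run.

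Of 31 lists with a test, 12 passed camera at a preset correlation of 0.01, 6 on the higher and 6 on the lower side. With a correlation estimated from the data 0 passed by camera after adjustment, 6 were under an unadjusted p of 0.05 and the smallest adjusted p was 0.0817, while the directional fry test, which does not compare a list with other genes, called 27.

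**Figure D3:**
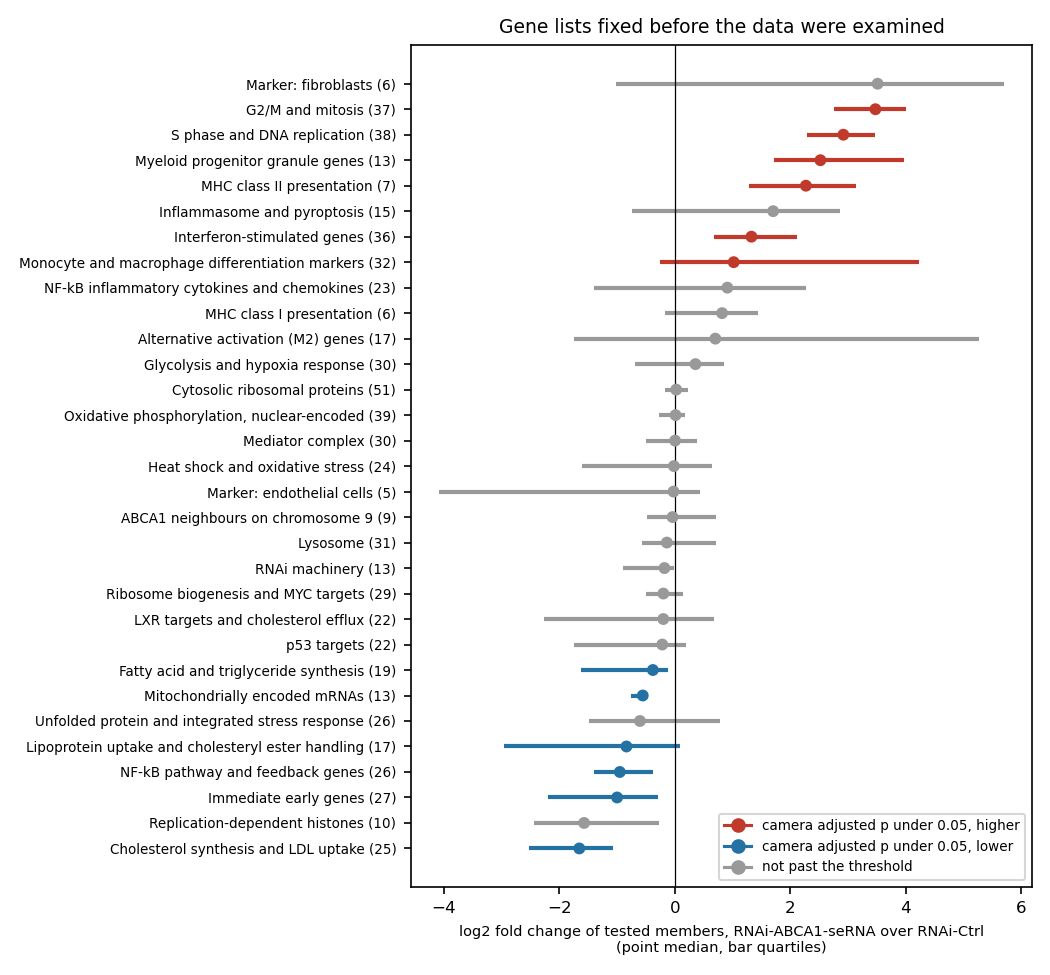
Median (point) and quartiles (bar) of the log2 fold change, RNAi-ABCA1-seRNA over RNAi-Ctrl, for the tested members of each of 31 gene lists, with the number of tested members in parentheses. Red and blue lists passed camera at a preset correlation on the higher and lower side, from G2/M and mitosis at 3.47 to cholesterol synthesis at -1.66, and grey lists did not; medians close to 0 change sign with the scaling.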

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

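The GC and length correction was the 1 test here that was chosen only after the result was seen. Counts of higher and lower genes stayed within 1.5 times of 4905 and 4720 under the other scalings, filters and tests, with GC and length trends removed (4538 and 5531), and without each library in turn (4572 to 5117 and 4372 to 4781), while an absolute log2 fold change of at least 1 left 2593 and 2087. No gene called in both reversed its direction under any of the alternatives fixed before the data were examined, and 20 did with GC and length trends removed. ABCA1 did not pass under any alternative fixed beforehand. Its log2 fold change of -0.13 was 0.075 with library totals alone, and between -0.26 and 0.058 without each library in turn (positive without RNAi-ABCA1-seRNA replicate 1). With GC and length trends removed it was 0.20 and passed, with an SE of 0.073 in place of 0.14. RNAi-ABCA1-seRNA replicate 1, the lowest library for ABCA1, also had the strongest length trend within its group (Spearman -0.529 across genes). The cause of these changes in ABCA1, that trend included, was not tested. The median of the LXR list was 0.0045 with library totals alone, and the cause was not tested. The fry test, asking only whether members move one way, called the LXR list (median -0.20, adjusted p = 6.93e-05) and the NF-kB cytokine list (adjusted p = 0.0300) on the lower side, the latter against its median of 0.91. Lists called numbered 12 by camera, 0 with an estimated correlation, 27 by fry and 11 to 13 under the other alternatives.

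Among 177 named genes, 2247 of 2284 alternative values kept direction and side of the threshold, 23 lost their call, 7 gained one and 7 reversed, for genes that did not pass. With library totals alone these were SREBF1 (0.056), NR1H3 (0.17) and PTGS2 (0.035). Without each library in turn PTGS2 ranged from -0.41 to 0.019, NR1H3 from -0.087 to 0.012 and IL1A from -0.025 to 0.25, and the causes were not tested. Whether replicate numbers paired the samples could not be told from 3 libraries per group. Deviations of same-numbered libraries from their group means correlated at 0.122, 0.137 and 0.0290 across genes. Libraries with different numbers gave -0.152 to 0.0347, and not every library correlated best with its own number. With the replicate number as a block 5032 genes were higher and 4897 lower, ABCA1 was at -0.15 (adjusted p = 0.0703 by edgeR's quasi-likelihood test), the LXR and NF-kB cytokine medians were -0.21 and 0.91, and 11 lists passed, without lipoprotein uptake (camera adjusted p = 0.0684). Depth limits genes near 0: with 3 counts at 0.125 to 0.162 CPM, differences below that level were not detectable.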

Other observations

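Tests of another cell line, of the scaling, of cell maturity and of the chromosome 6 region were chosen only after the result was seen. The GC and length correction, used below as well, was also added after seeing the data. Genes with the highest CPM, which is not adjusted for transcript length, also shifted between the groups and were named after their values were seen. ACTB, the cytoplasmic actin gene, rose from 5051 ± 143 to 12117 ± 672 CPM (log2 fold change 1.26 ± 0.066) and had the highest mean CPM in RNAi-ABCA1-seRNA. MMP9, a gelatinase of macrophages, rose from 4194 ± 20.2 to 8234 ± 759.7 CPM (log2 fold change 0.97 ± 0.075). CHI3L1, a secreted chitinase-like protein of macrophages, fell from 6507 ± 175 to 2314 ± 115 CPM (log2 fold change -1.49 ± 0.066) and SOD2, the mitochondrial superoxide dismutase, fell from 4993 ± 141 to 3437 ± 230.3 CPM (log2 fold change -0.54 ± 0.069). PSAP, the precursor of lysosomal lipid-binding saposins, rose from 3214 ± 54.6 to 4385 ± 272 CPM (log2 fold change 0.45 ± 0.067). The 10 genes with the most counts in each library held 6.75% to 7.27% of its counts. Within the RNAi-ABCA1-seRNA group, the deviation of replicate 1 from the group mean correlated with transcript length at Spearman -0.529 across genes, against 0.433 and 0.235 in replicates 2 and 3, and genes are not independent replicates.

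For the breadth of the difference, 9625 of 12832 tested genes and the first pattern weighed, GC and length trends of the libraries as the whole cause are argued against, since their removal left 104.6% of the count of called genes, with 92.1% of the called genes shared, and so are gains or losses of whole chromosomes as the whole cause, since at most 67.1% of called genes went the same way on any of 23 chromosomes (highest upper 95% limit 74.4%). Some chromosomes leaned one way, with 165 genes higher and 337 lower on chromosome 5, 399 and 691 on chromosome 1, 34 and 63 on chromosome 21, and 433 and 253 on chromosome 19, so a contribution of copy number there stays open. The 10 possible splits of 3 against 3 are too few for a share under 0.05: the real split gave 9625 genes and 1 split reached that number, itself, while the highest other gave 0. CDKN2A, CDKN2B and MTAP, which THP-1 is known to lack, had 0 counts in the 6 libraries, but another line with that loss would show the same, and genes known to be widely used were also at 0 in this table, so a difference in line cannot be told apart from the other differences between the groups. An effect of the RNAi, or of carrying an RNAi construct if control cells had none, likewise stays open and untested. So does a difference in culture, stimulation or growth state between the groups, because each of these would follow the groups.

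Cell cycle genes, all 37 of the G2/M list and 37 of 38 of the S phase list, were higher in RNAi-ABCA1-seRNA. The G2/M median was at least 3.46 under 3 scalings. A change of scaling shifts all genes nearly alike, by 0.21 at most here, so it moved this median little. That test could not have come out otherwise, and no conclusion is drawn from it. GC and length trends fitted over all genes are argued against as the whole cause, since the median was 3.29 after their removal. That removal takes out only what genes of like GC content and length share, so other forms of such bias were not tested. A state in which the RNAi-ABCA1-seRNA cells were uniformly less mature, which could go with more division and more granule transcripts, is argued against by the monocyte and macrophage markers, whose median was 1.02 on the higher side, although 10 of 32 fell. A candidate explanation that stays open is that the RNAi-Ctrl cells divided less, through the RNAi difference or through their culture, and the design holds no measurement that parts these.

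Most genes of the MHC region of chromosome 6, 140 of 150, were at or near 0 in all 6 libraries. Of 36 genes of the region that nearly all cells use, 91.7% (exact 95% interval 77.5% to 98.2%) had 10 counts or fewer over the libraries, against 7 of 131 ribosomal, oxidative phosphorylation and Mediator genes elsewhere (5.34%). Loss of the region from the cells is argued against by 13844 counts of HLA-DRB1, which lies inside it between near-0 genes. The values are consistent with counts lost for genes that also lie on alternate haplotype sequences of the build, by read placement or by how copies were merged, and which of these may apply was not tested. No biological explanation other than loss of the region was tested, and TNF, HSPA1A and HLA-DRA, at 0 counts here, could not be assessed.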
